A study of Mus musculus with 2 samples.

How the data were processed

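DNase-seq was analysed in 2 libraries from the adrenal gland of female B6CASTF1/J mice aged 4 days. DNase I cuts DNA where chromatin is open, so that a local excess of cuts marks an accessible region and a short stretch of protected bases inside such a region marks a footprint. B6CASTF1/J mice are first-generation hybrids, and alleles were not separated here. The labels name the libraries as biological replicates 1 and 2 of 1 group. The sample descriptions mention 3 females per sample, and both samples carry the same donor identifier, so how the tissue was pooled is not given in the sources used here. There is no second group, and no test between groups was made. With n = 2, values are given per library.

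Each library came with 2 peak lists, 1 list of footprints and 1 list of false discovery rates, all on assembly mm10 per the labels. The peak lists were called per library, and each holds 1 deposited signal value per peak, which is the authors' own value for that peak. Its scaling is not given in the sources used here. Within a library the deposited signal values were whole multiples of 1 step, 0.00853 in replicate 1 and 0.00880 in replicate 2, for 100% of 46031 and 100% of 87387 values at a tolerance of 0.05 steps. Signal is therefore used to describe peaks as the authors scaled it, and values are set side by side across libraries only in that form. Genes and shared peaks were ranked by the mean of the 2 deposited values. The values of replicate 2, which were mostly higher, weigh more in that mean. The deposited lists of false discovery rates hold adjusted p-values of the local cut rate, only below 0.05. Every peak of the longer list of a library overlapped a position below 0.05, and every peak of the shorter list overlapped one below 0.001, so the longer list served as the main set and the shorter as the stricter one. The deposited footprint lists carry the same value of 0.01 in every entry, taken as a p-value threshold; they hold no score per footprint. The tools that made these lists, the read depth and the filters are not given in the sources used here. The counting error behind a single peak could therefore not be computed.

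Chromosomes 1 to 19, X and Y were kept. Positions were set against the reference GRCm38.p6, the build of mm10, with GENCODE release M21; 0 peaks reached past a chromosome end. The reference is a C57BL/6J sequence, so reads from the other parental genome were placed on it as well. Coordinates are given 1-based.

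Peaks were compared between libraries by an overlap of at least 1 bp, and overlaps were set against 100 circular shifts of one set along each chromosome. Shared peaks are the replicate 2 peaks overlapped by a replicate 1 peak. Spearman's and Pearson's coefficients were taken across peaks that overlapped 1 to 1; peaks are not independent replicates. A peak counted as a promoter peak when its centre lay within 1 kb of any annotated transcription start site (TSS), and as distal otherwise. A protein-coding gene on chromosomes 1 to 19 or X had an accessible promoter when a peak overlapped the 1 kb to either side of one of its TSSs in both libraries. The peaks of the 2 libraries did not have to overlap each other. Any annotated TSS counted, also one inside the gene, and the signal given is that of the strongest such peak. At Por, Ctnnb1 and Nr4a1, among others, that peak lay inside the gene, over 1 kb from its 5′ end. Distal peaks were assigned to the gene of the nearest protein-coding TSS.

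The 18 gene lists, with 204 members, cover steroidogenesis and cholesterol supply, cholesterol synthesis, cortex identity and zonation, medulla chromaffin, Schwann and neural crest, endothelial, leukocyte, erythroid, capsule and fibroblast, kidney, adipocyte, liver, skeletal muscle, gonad, photoreceptor, housekeeping, immediate early and cAMP response, and imprinted genes. Promoter shares were tested per list against all other protein-coding genes with a two-sided Fisher's exact test. Mean numbers of distal peaks per gene were tested against 10000 random lists matched on decile of territory, the length of sequence closest to a gene's TSSs. Motifs were 25 consensus strings searched on both strands in 200 bp windows around peak centres. Control windows lay 2 kb to either side and overlapped no peak. Footprints were widened to at least 20 bp and set against windows shifted by 40 bp inside the same peaks. Motifs were tested with two-sided Fisher's exact tests and called enriched at an adjusted p below 0.05 and an odds ratio of at least 1.5. Odds ratios carry Woolf's 95% interval, with 0.5 added to each cell where a cell was 0. All p-values were adjusted by Benjamini and Hochberg's method over the 18 lists or the 25 motifs. Genes, peaks and windows are not biological replicates, and these tests describe the 2 libraries.

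The design, lists, motifs and alternatives were fixed before the data were examined, apart from 1 alternative that matched random genes on promoter CpG content. That content was taken within 500 bp of the annotated TSS with the lowest coordinate of each gene, whatever its strand. For genes on the minus strand with several TSSs this is the most downstream one, so the match on promoters is rough. By the rule fixed before the data were examined, the genes named are Nr5a1, Star, Cyp11a1, Cyp21a1, Mc2r, Th, Pnmt and Xist. To these were added, per list, the 2 members with the highest mean TSS signal and up to 2 members with no TSS peak in either library, in alphabetical order. The rule also took the 5 genes with the most distal peaks and the 5 shared distal peaks with the highest mean signal over both libraries. Results for some genes that the rule takes are not reported. Motifs named are the 5 with the highest and the 3 with the lowest odds ratio per test, with a scrambled NR5A string as control. The NR5A motif is given as well, and the other enriched motifs of each test were added after their values were seen.

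The alternatives left out each replicate, used the stricter peaks, equal numbers of peaks, 50% reciprocal overlap, TSS windows of 500 bp and 2.5 kb, a peak in either library, peaks within 50 kb of the gene body, 100 bp windows, a GC-matched background in 2% bins, and footprints inside peaks. The scripts were tested on simulated data. Of 40000 simulated intervals, 75.2% were found overlapped where 75% had been planted. For the promoter test on 21755 genes, 83.3% of changed lists and 0.500% of unchanged lists were called. The changed lists held 8 to 22 genes and the rate was not split by size, so it is no measure for the smallest lists. The distal test called 63.3% of lists simulated at 3 times the rate and 0.667% of unchanged lists. All 3 planted motifs and 0 of the others were called. The signal ratio test called 100% of lowered lists and 1.67% of unchanged lists. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and bedtools 2.31.1 for reciprocal overlaps.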

Results

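Accessible chromatin was mapped by DNase-seq in the adrenal gland of female mice aged 4 days, in 2 libraries labelled as biological replicates of 1 group. The gland holds a steroid-producing cortex around a medulla of chromaffin cells, which make catecholamines, together with vessels, nerves and a fibrous capsule. The labels state no purpose beyond mapping open chromatin in this tissue, so the comparisons asked how far the 2 libraries gave the same regions, where those regions lay, and at which genes. Read depth is not given in the sources used here.

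Replicate 2 held 1.90 times as many peaks as replicate 1. Replicate 1 had 46031 peaks covering 9.52 Mb, with a median width of 190 bp, and replicate 2 had 87387 peaks covering 14.96 Mb, with a median width of 160 bp. The mean was 66709 ± 29243 peaks (SD, n = 2). Footprints numbered 98364 in replicate 1 and 141983 in replicate 2, a ratio of 1.44, with a mean of 120174 ± 30843 (SD, n = 2) and a median width of 9 bp in both. Of these, 92.7% in replicate 1 and 93.5% in replicate 2 overlapped a peak of the same library. At the stricter threshold the libraries held 27765 and 50406 peaks.

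Replicate 2 contained most of the regions found in replicate 1. Of the replicate 1 peaks, 83.9% were overlapped by a replicate 2 peak, against a mean of 1.28% and a maximum of 1.49% after 100 circular shifts. In the other direction 44.9% of replicate 2 peaks were overlapped, against 0.676% after shifting. The peaks of replicate 2 that were missed in replicate 1 were mostly weak ones. With replicate 2 peaks divided by signal into 5 groups of equal size, 2.15% of the weakest group and 98.0% of the strongest were found in replicate 1. Across 34770 peaks that overlapped 1 to 1, signal was correlated between the libraries, with a Spearman coefficient of 0.897 and a Pearson coefficient of 0.900 on the log10 scale; peaks are not independent replicates. Footprints overlapped less than peaks. Of the replicate 1 footprints, 50.3% were overlapped by a replicate 2 footprint, against 0.125% after shifting, and the share was 57.6% among those inside replicate 2 peaks. When at least 50% of both footprints had to overlap, the share was 32%.

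**Figure D1:**
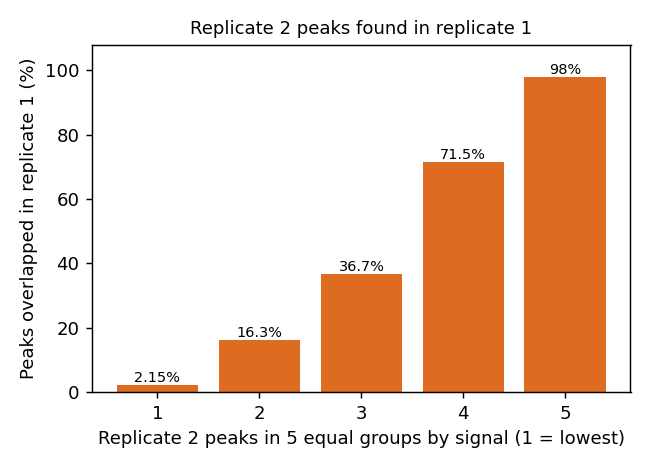
Share of replicate 2 peaks, in percent, that were overlapped by at least 1 bp by a replicate 1 peak (vertical axis), in 5 groups of replicate 2 peaks of equal size ordered by deposited signal (horizontal axis). The share went from 2.15% in the weakest group to 98.0% in the strongest.

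Most regions present in both libraries lay at promoters. Of the 39266 shared peaks, 22163 were centred within 1 kb of a TSS, or 56.4%, against a mean of 6.22% after 100 circular shifts. Of the shared peaks, 3.75% lay in exons, 19.2% in introns and 20.6% between genes, outside the promoter windows. For random genome positions these shares were 3.11%, 37.2% and 53.9%, with 5.87% within 1 kb of a TSS. The promoter share of all replicate 2 peaks was 37.4%, and 21.8% of the 48121 peaks found in replicate 2 alone lay at promoters. In replicate 1 the promoter share was 53.5%. Median signal of shared peaks, as the mean over both libraries, was 1.98 at promoters and 1.38 in introns.

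The promoter of Nr5a1, which encodes steroidogenic factor 1, a regulator of steroid-producing cells, was accessible in both libraries, though not in the stricter list of replicate 1. Its peak, at chromosome 2 from 38714441 to 38714620 in replicate 2, had a signal of 1.77 in replicate 1 and 5.07 in replicate 2. Several genes of steroid synthesis had weaker or no TSS peaks. Cyp11a1, the cholesterol side-chain cleavage enzyme, had a peak of 1.254 and 3.54 at chromosome 9 from 58014921 to 58015120, over its annotated TSS at 58014997. The stricter list of replicate 1 lacked this peak. No peak lay at the most upstream annotated TSS, 58006411, and which TSS is used in this tissue was not tested. Star, which carries cholesterol into mitochondria, had a TSS peak in replicate 2 alone, with a signal of 2.73, inside the gene and not at its 5′ end. Cyp21a1, the 21-hydroxylase, also had one in replicate 2 alone, with a signal of 1.12; a pseudogene copy lies close by, so this value is uncertain. Mc2r, the receptor for adrenocorticotropic hormone, had no TSS peak in either library and 4 shared distal peaks. These lay 64681 to 365351 bp from its TSS in a territory of 503 kb, so their assignment to Mc2r is uncertain. Xist, the non-coding RNA of the inactive X chromosome, had peaks near a TSS at places that did not overlap between the libraries. The signal was 0.870 from 103483161 to 103483320 in replicate 1 and 1.249 from 103484181 to 103484340 in replicate 2.

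**Figure D2:**
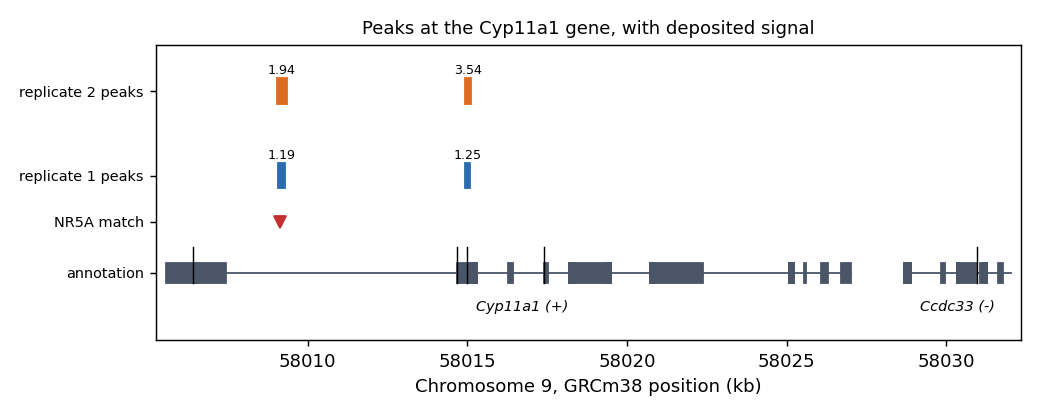
Map of Cyp11a1 on chromosome 9 of GRCm38 (horizontal axis, kb), with exons of all annotated transcripts as boxes, TSSs of protein-coding genes as vertical lines, and peaks of replicates 1 and 2 as coloured boxes with their deposited signal. The triangle marks an NR5A consensus match inside the intronic peak, whose signal was 1.19 in replicate 1 and 1.94 in replicate 2.

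Genes of cholesterol synthesis had accessible promoters throughout, and genes of steroidogenesis did not stand apart from other genes. Over all 21755 protein-coding genes, 13346 (61.3%) had a TSS peak in both libraries. Of the 18 lists, 8 differed from other genes, 3 with higher and 5 with lower shares (two-sided Fisher's exact test, adjusted p below 0.05). All 12 cholesterol synthesis genes had such a peak, led by Insig1 with a signal of 4.84 and 10.4 and Dhcr7 with 4.54 and 8.78, both within 1 kb of a TSS of another gene, Nadsyn1 in the case of Dhcr7. The steroidogenesis and cholesterol supply list had 9 of 15. The electron carriers of the pathway led it, Por with 3.45 and 9.61 and Fdxr with 3.37 and 8.20, and the enzymes Cyp11b1 and Hsd3b1 had no TSS peak. Among cortex identity and zonation genes, 14 of 20 had a peak. Cited2, a transcriptional co-regulator, reached 3.90 and 10.6 and Ctnnb1, encoding β-catenin, 4.07 and 7.26, while Akr1c18 and Pik3c2g had none. In Fisher's exact test the adjusted p was 0.0176 for cholesterol synthesis, 1 for steroidogenesis and cholesterol supply, and 0.527 for cortex identity and zonation genes. Random lists matched on promoter CpG content were an alternative chosen after the data were seen. Against them cholesterol synthesis genes stood at 100% against 81.1% (adjusted p of 0.260). The upper bound of these random lists was itself 100%, and with all 12 genes open the unadjusted p was 0.116. The list could therefore not have been called higher, and whether CpG content accounts for its call was not decided.

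Medulla chromaffin genes had accessible promoters at 17 of 22 members (Fisher's exact test, adjusted p = 0.281), though those of several catecholamine enzymes were not called. Chgb, a chromogranin of secretory granules, had a signal of 2.85 and 8.12. The peak of 4.25 and 10.4 at Slc18a1, a vesicular monoamine transporter, lay within 1 kb of a TSS of Atp6v1b2 and cannot be assigned to one of them. Of the genes for enzymes of catecholamine synthesis, Th, Dbh and Pnmt had no TSS peak in either library, while Ddc, named after its values were seen, had one of 0.606 and 0.862. Th had 3 shared distal peaks, the strongest at chromosome 7 from 142919341 to 142919500 with 1.97 and 5.14.

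Markers of leukocytes and kidney, which the dissected gland could hold, had accessible promoters at a lower share than other genes, a difference that did not pass the threshold against CpG-matched lists. Leukocyte genes had TSS peaks in both libraries at 1 of 10, the peak of Ptprc, with 0.367 and 0.405, which was not in the stricter lists. In replicate 2 it lay at chromosome 1 from 138120118 to 138120182, inside the gene and away from its 5′ end at 138175708. Spi1 had a peak of 0.836 in replicate 1 alone and Adgre1 and Cd3e had none. Kidney genes had them at 2 of 12, Lrp2 with 0.699 and 0.730 and Pax8 with 0.469 and 0.642, of which the stricter lists held Lrp2 in replicate 1 alone, and none at Aqp2 and Cdh16. The other 5 lists of cell types in or near the gland did not pass the test. Endothelial genes had peaks at 5 of 12, with Egfl7 at 1.31 and 2.60, Flt1 at 1.13 and 1.63, and none at Emcn and Pecam1. Erythroid genes had 2 of 8, with none at Alas2 and Epb42. Among them was Tal1, with 0.981 in replicate 1 and 0.862 in replicate 2 at places that did not overlap. Capsule and fibroblast genes had 3 of 9, with Col1a1 at 1.76 and 3.92, Pdgfra at 1.67 and 3.34, and none at Acta2 and Dcn. Schwann and neural crest genes had 4 of 8, with Erbb3 at 1.43 and 2.04 and none at S100b. Adipocyte genes had 4 of 8, with Lipe at 2.87 and 8.46, Plin1 at 1.03 and 4.05, and none at Adipoq and Fabp4. The stricter list of replicate 1 lacked the peaks at Egfl7, Tal1 and Plin1. The peaks at Egfl7, Pdgfra and Lipe also lay within 1 kb of a TSS of another gene. Those at Egfl7, Pdgfra, Plin1 and Lipe lay inside the annotated gene, over 1 kb from its 5′ end. In Fisher's exact test the adjusted p was 0.0113 for leukocyte, 0.0124 for kidney, 0.324 for endothelial and 0.124 for erythroid genes, 0.159 for capsule and fibroblast genes, and 0.527 both for Schwann and neural crest and for adipocyte genes. With the stricter peaks endothelial and erythroid genes passed the same test with lower shares, at 0.0179 and 0.00524, and with TSS windows of 2.5 kb kidney genes did not, at 0.0934. Erythroid genes also passed with equal peak numbers and with windows of 500 bp, at 0.0276 and 0.0169. Against CpG-matched lists leukocyte genes stood at 10% against 40.7% (adjusted p of 0.215) and kidney genes at 16.7% against 51.6% (adjusted p of 0.0990).

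No liver gene had an accessible promoter in both libraries, and all housekeeping, immediate early and imprinted genes tested did. Of the 10 liver genes, 0 had a TSS peak in both libraries; Apoa1 had one of 0.299 in replicate 2 alone, and Ahsg and Alb had none. Skeletal muscle genes had 2 of 10, Ckm with 1.63 and 5.32 and Actn3 with 3.23 and 7.26, the latter within 1 kb of a TSS of Zdhhc24, while Acta1 and Myf5 had none. Photoreceptor genes had 2 of 10, Gnat1 with 1.79 and 3.61 and Opn1sw with 0.699, not in the stricter list, and 1.82, and Crx and Nrl had none. The peak at Gnat1 lay inside the gene, over 1 kb from its 5′ end. Gonad genes had 4 of 8, with Amh at 2.09 and 4.86 but no peak within 500 bp of a TSS, Sox9 at 1.16 and 2.67 within 1 kb of a TSS of another gene, and none at Fshr and Hsd17b3. All 12 housekeeping genes had a peak. Actb with 4.48 and 11.2 and Polr2a with 4.45 and 9.78 led them in mean signal over both libraries, though not in replicate 1. The peaks given for Polr2a did not overlap between the libraries. All 10 immediate early and cAMP response genes had a peak. Egr1 with 3.85 and 10.4 and Nr4a1 with 3.43 and 9.87 led these in mean signal, though not in replicate 1. All 6 protein-coding imprinted genes had one, led by Peg3 with 1.79 and 5.56, within 1 kb of a TSS of Usp29, and Cdkn1c with 1.73 and 4.41; of the non-coding members outside the test, Meg3 had 1.31 and 2.34 and H19 had none. In Fisher's exact test the adjusted p was 0.00134 for liver, 0.0387 for skeletal muscle and for photoreceptor, and 0.527 for gonad genes. It was 0.0176 for housekeeping, 0.0264 for immediate early and cAMP response, and 0.159 for imprinted genes. With all 6 imprinted genes open, the unadjusted p of this test was 0.0884, so a list of that size could not have been called higher. Against CpG-matched lists 1 of the 18 lists differed, the liver list, with 0 against 49.2% (adjusted p of 0.0216). Skeletal muscle genes stood at 20% against 50.3% (adjusted p of 0.222) and photoreceptor genes at 20% against 59.3% (0.0990). Housekeeping genes stood at 100% against 73.2% (0.111) and immediate early genes at 100% against 86.2% (0.679). With all 12 housekeeping genes open, their unadjusted p of 0.0308 against CpG-matched lists was the lowest this list could reach. Beside the p-values of the other lists it could not have been called higher, so whether CpG content accounts for the housekeeping call was not decided. For immediate early genes the upper bound of the random lists was itself 100%, with an unadjusted p of 0.417. With all 10 genes open, that list could not have been called higher against CpG-matched lists. In Fisher's exact test the call for skeletal muscle also ended with the stricter peaks (0.0914), with 50% reciprocal overlap (0.114) and with TSS windows of 2.5 kb (0.277). That for photoreceptor genes ended with reciprocal overlap (0.114), and that for immediate early genes with a peak in either library (0.0824) and with windows of 2.5 kb (0.0517). Gonad genes passed it with TSS windows of 500 bp, with a lower share and adjusted p at 0.0169.

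**Figure D3:**
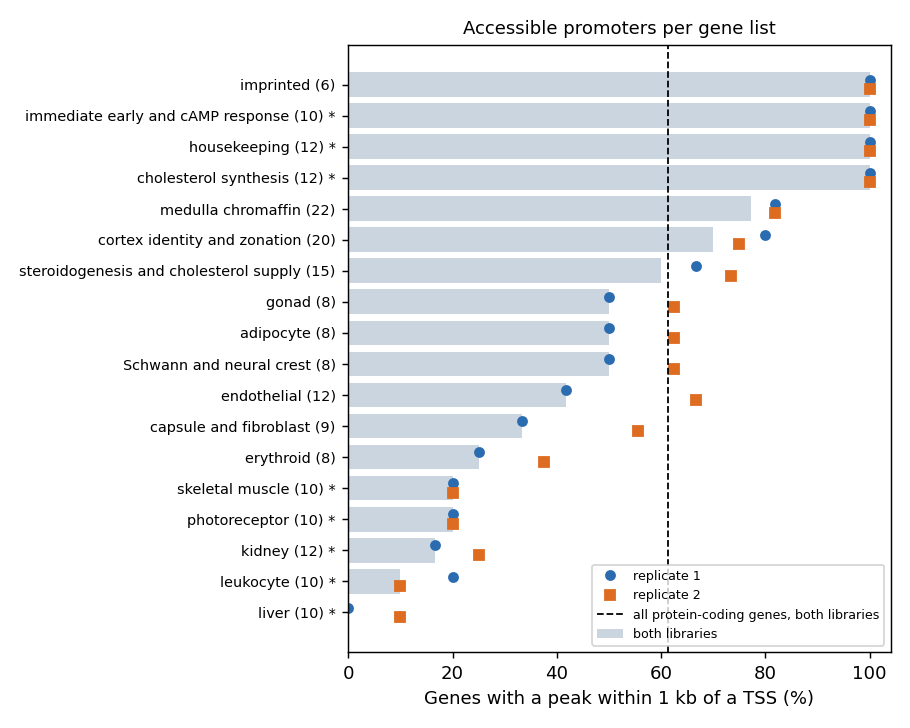
Share of genes, in percent, with a peak within 1 kb of a TSS (horizontal axis) in each of the 18 lists, with the number of genes tested in brackets; bars show peaks in both libraries, circles replicate 1 and squares replicate 2. Stars mark the 8 lists that differed from other genes, and the dashed line is the 61.3% of all protein-coding genes.

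Distal peaks did not separate the lists. Of 17103 shared distal peaks, 17071 were assigned to a protein-coding gene, a mean of 0.785 per gene. None of the 18 lists differed from matched random lists at an adjusted p below 0.05, and 4 did at an unadjusted p below 0.05, all with more peaks. Immediate early and cAMP response genes had a mean of 2.90 distal peaks, 2.81 times the matched mean (adjusted p of 0.0972), and this list passed with equal peak numbers (3.13 times, adjusted p of 0.0468) and within 50 kb of the gene body (3.06 times, adjusted p of 0.00360). It stood at 1.76 times without replicate 1 (adjusted p of 0.694), 2.33 times without replicate 2 (0.194), 2.18 times with reciprocal overlap (0.293) and 3.35 times with the stricter peaks (0.0828). Steroidogenesis and cholesterol supply genes had 1.67, or 2.47 times (adjusted p of 0.0972), and 1.64 to 3.21 times under the alternatives. Few genes carried this mean: of the 25 peaks Scarb1 had 9 and Cyp21a1 and Mc2r 4 each, while 6 of the 15 genes had none. Housekeeping genes stood at 2.58 times (adjusted p of 0.149), imprinted genes at 2.40 times (adjusted p of 0.187), and capsule and fibroblast genes at 1.81 times (adjusted p of 0.376). Without replicate 1 these stood at 1.66 for housekeeping and 1.096 for capsule and fibroblast genes. Ratios near or below 1 were found for cortex identity and zonation genes (0.962, adjusted p of 0.998) and medulla chromaffin genes (0.720, adjusted p of 0.793). For the other lists the ratio was 0.803 for cholesterol synthesis, 0.305 for Schwann and neural crest, 1.19 for endothelial, 0.616 for leukocyte, 0.408 for erythroid and 1.58 for kidney genes. It was 0.466 for adipocyte, 1.15 for liver, 1.1 for skeletal muscle, 1.06 for gonad and 0.468 for photoreceptor genes. Several of these moved without replicate 1, to 1.31 for cholesterol synthesis, 0.523 for Schwann and neural crest, 0.966 for erythroid, 0.797 for kidney and 1.44 for adipocyte genes, and without replicate 2, to 0.481 for Schwann and neural crest and 0.796 for adipocyte genes.

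Among the genes with the most shared distal peaks were Tns1 with 21, Sfi1 with 20, Gm15319 with 18 and Nfic with 18. The territory of Sfi1, 3198 kb, was counted from the start of chromosome 11, while the gene lies from 3131850 to 3193463. That length is therefore no guide to the count of Sfi1, which stays uncertain. By mean signal over both libraries, the strongest shared distal peak lay on chromosome 15 from 99735641 to 99736040, in an exon 10223 bp from the nearest TSS, of Cox14. Its signal was 42.3 in replicate 1 and 39.4 in replicate 2, where the peaks nearest to Lars2 and Igf2bp3 stood higher. The next lay on chromosome 9 from 123461921 to 123462080, in an exon 7211 bp from a TSS of Lars2, with 29.8 and 43.9. The third lay between genes on chromosome 6 from 49236441 to 49236620, 21574 bp from a TSS of Igf2bp3, with 24.7 and 44.7. On chromosome 13, a peak in an intron from 112578161 to 112578320 lay 2421 bp from a TSS of Il31ra, with 20.4 and 31.4. Another on chromosome 13, in an exon from 58177641 to 58177800, lay 3904 bp from a TSS of Ubqln1, with 21.9 and 24.9. The peaks nearest to Lars2, Igf2bp3 and Il31ra hold sequence found more than once in the assembly.

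CTCF and REST motifs had the highest odds ratios of the 25 motifs in distal peaks, and their order depended on the setting. A CTCF consensus stood in 18.0% of 200 bp windows around shared distal peaks and in 0.0831% of flanking windows, an odds ratio of 263 (95% interval 180 to 384). In all, 10 motifs passed the threshold of enrichment, and the others with the highest odds ratios were REST (135, interval 18.8 to 975, which spans that of CTCF), NRF1 (55.2, 7.51 to 405), NFI (15.7, 5.56 to 44.3) and YY1 (9.50, 2.08 to 43.4). Without replicate 1 CTCF stood at 119, REST at 197 (27.5 to 1413), NRF1 at 10.6, NFI at 27.9 and YY1 at 3.39. With 100 bp windows CTCF stood at 875. The other enriched motifs were SP/KLF (4.30), CRE (3.202), AP-1 (2.03), the E-box (1.92, in 17.3% of windows) and the glucocorticoid and androgen response element (1.55). Against GC-matched windows CTCF stood at 227, NRF1 at 4.47, NFI at 8.26 and YY1 at 5.0, and REST had 71 peak windows and 0 control windows. There SP/KLF fell to 1.68 and the E-box to 1.31, below the threshold. CRE rose to 5.62 in the stricter peaks. The response element was enriched under no alternative but GC matching (1.71). The motif of NR5A factors, which include steroidogenic factor 1, stood in 3.79% of distal windows and 2.67% of flanks, an odds ratio of 1.44 (1.29 to 1.59) below the threshold of 1.5. Its scrambled control had 1.36 (1.15 to 1.60), an interval that overlaps it. The lowest odds ratios were those of PHOX2 (0.492, 0.214 to 1.13), PBX (0.618, 0.477 to 0.801) and GATA (0.728, 0.658 to 0.806). Against GC-matched windows PHOX2 turned to 7.0, on 7 peak windows, and GATA to 1.12, PBX was at 0.956, while NR5A stood at 1.68, past the threshold, and its control at 1.22. NR5A also passed in each library alone, at 1.71 in replicate 2 and 1.53 in replicate 1, and turned to 0.984 in the stricter peaks. With 100 bp windows both the NR5A motif, at 1.67, and its control, at 1.55, passed.

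**Figure D4:**
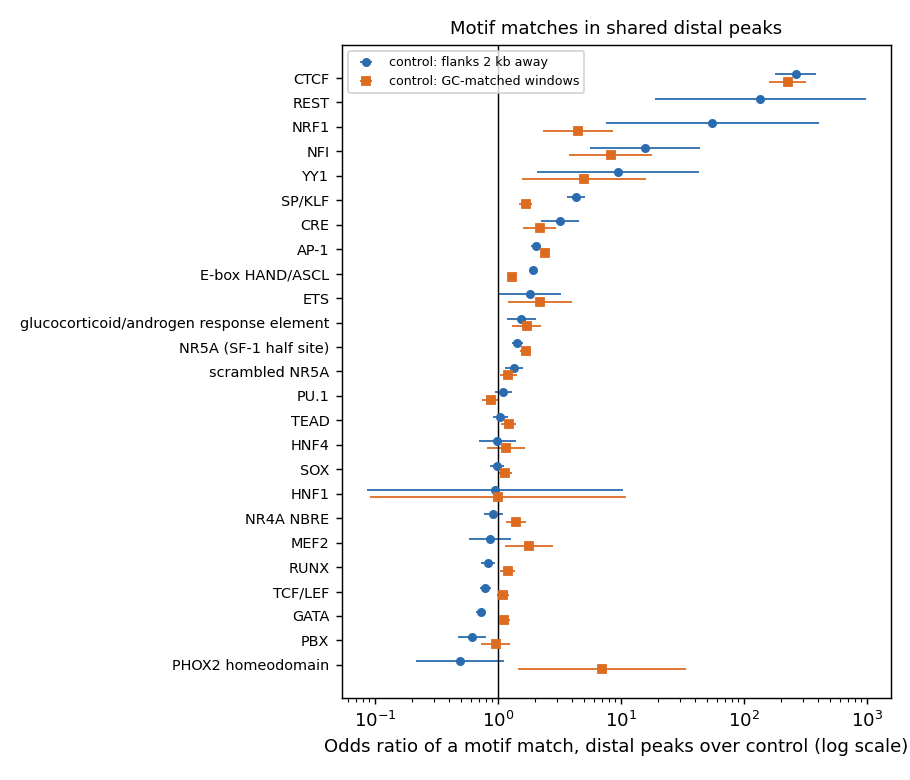
Odds ratio of a consensus match in 200 bp windows around shared distal peaks over control windows (horizontal axis, log scale), for each of the 25 motifs, with bars for the 95% interval. Circles use flanks 2 kb away and squares GC-matched windows, without REST, which stood in 0 of those; CTCF stands at 263 against flanks.

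Motifs of NRF1, REST, YY1, SP/KLF, ETS, CTCF, CRE and NFI, 8 of the 25, were enriched in shared promoter peaks, but NFI, with 10 windows against 6, was not enriched with the stricter peaks (3.33, 0.975 to 11.4). NRF1 stood in 301 windows and REST in 33, each against 0 flanking windows, which is at least 190-fold and 20.8-fold higher if the flanks are set at 3 matches over all of them. YY1 had an odds ratio of 120 (38.4 to 376), SP/KLF one of 28.1 (24.8 to 31.7) and ETS one of 27.1 (17.0 to 43.2). Without replicate 2 ETS stood at 16.9. SP/KLF matches stood in 16.05% of promoter windows. The lowest were PHOX2, with 0 promoter windows against 31 flanks, HNF1, with 0 against 8 (adjusted p = 0.0573, Fisher's exact test), and GATA with 0.236 (0.206 to 0.269). The scrambled control stood at 0.664 (0.547 to 0.805) and the NR5A motif at 0.424 (0.373 to 0.482). Against GC-matched windows, which could be had for 13742 of the 22163 promoter windows, GATA turned to 1.05 and NR5A stood at 0.976. Most of the enriched motifs named here had lower odds ratios against them: NRF1 31.5 (17.1 to 57.9), YY1 25.3, SP/KLF 3.95 and ETS 23.1, with REST in 27 windows against 0. CRE also fell, from 15.1 to 13.4, while CTCF rose from 22.7 to 29.0 and NFI from 3.16 to 4.00.

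Footprints overlapped the consensus strings of 8 motifs more often than windows 40 bp away in the same peaks. CTCF matches overlapped 7.50% of shared footprints and 0.0432% of shifted windows, an odds ratio of 188 (117 to 302). NRF1 stood at 86.4 (27.7 to 270), REST at 86.3 (12.04 to 619) and CRE at 14.6 (9.73 to 21.8). NFI overlapped 31 footprints and 0 shifted windows, at least 8.99-fold higher with the shifted windows set at 3 matches. SP/KLF stood at 8.004 (7.07 to 9.06), in 5.48% of footprints, ETS at 2.52 (1.79 to 3.55) and YY1 at 1.72 (1.16 to 2.55). The lowest were PHOX2, with 0 footprints against 2 windows, GATA (0.355, 0.264 to 0.479) and the glucocorticoid and androgen response element (0.421, 0.227 to 0.780). Leaving out a library changed several of these: CTCF stood at 56 without replicate 1 and 88.6 without replicate 2, NRF1 at 23.7 and 24.4, and CRE at 6.91 and 10.4. REST stood at 52.0 and 119, and SP/KLF at 4.95 and 4.21. GATA rose to 0.497 and 0.576 and the response element to 0.636 and 0.658. The NR5A motif had an odds ratio of 1.27 (0.994 to 1.63) and its scrambled control 1.07 (0.764 to 1.51).

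The X chromosome held fewer peaks per Mb than the autosomes in both libraries. In replicate 1 it had 8.24 peaks per Mb against a median of 18.3 over the autosomes, which ranged from 13.6 to 29.1. In replicate 2 it had 17.1 against 36.2, with a range from 25.1 to 53.7. The ratio was 0.451 and 0.473, a mean of 0.462 ± 0.0155 (SD, n = 2), and no test was made. With the stricter peaks it was 0.343 and with equal peak numbers 0.359.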

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

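Both tests in this part were chosen after the result was seen. Chromosome Y carried 48 peaks in replicate 1 and 81 in replicate 2, although the labels give the animals as female. These peaks were singled out because female tissue should give no signal there; they are part of the peak totals and overlaps of the report, but chromosome Y entered no test of gene lists. They made up 0.104% and 0.0927% of all peaks, with a median signal of 0.252 and 0.176 and a highest signal of 4.35 and 7.20.

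Cells of male animals in the sample would open the promoters of broadly expressed Y genes. Of Ddx3y, Uty, Kdm5d and Eif2s3y, 0 had a TSS peak in either library, and 0 positions below a false discovery rate of 0.05 lay within 1 kb of their TSSs, which argues against male cells as the source of the Y peaks. Sequence shared with other chromosomes may account for many of them: a median of 56.2% of their 32-mers also occurred on another chromosome, against 9.09% in 1000 random windows of chromosome Y, a comparison that was added last. Over 50% of 32-mers were shared in 26 of 48 and 45 of 81 peaks, and none in 6 and 13 peaks, whose origin stays open. Male cells were judged at the TSSs of the named Y genes alone, and a small share of such cells is not excluded. Beyond male cells, no biological explanation was tested.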

How the results depend on the processing

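The CpG-matched random lists were chosen after seeing the data; the other alternatives were fixed before. No paired analysis was possible because there is 1 group. Equal numbers of footprints were not run, since footprints carry no score, and overlaps and correlations need both libraries. The Spearman coefficient kept to 0.877 to 0.887, and the numbers of enriched motifs were 9 to 13 in distal peaks, 7 to 9 in promoter peaks and 8 in footprints. Where a value below differed from that of the report the cause was not tested, unless fewer peaks or a narrower definition enter by construction.

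With the stricter peaks the mean number of peaks was 39085.5, the overlap of replicate 1 by replicate 2 was 89.8% and the X density ratio was 0.343. With equal peak numbers the overlap was 73.8% and the X ratio 0.359. With 50% reciprocal overlap the overlap was 68.0% for peaks and 32% for footprints. The share of peaks within 1 kb of a TSS ranged from 37.4% to 53.5% without replicate 1 or 2, and from 49.0% to 65.9% otherwise. The number of lists with a different promoter share was 5 with TSS windows of 2.5 kb and 1 with CpG-matched lists, and 6 to 10 otherwise. The number of lists with a different number of distal peaks was 1 with equal peak numbers, 1 within 50 kb of the gene body and 0 otherwise.

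None of the lists below passed the threshold in the report or under the alternative that turned its direction. The promoter odds ratio of steroidogenesis and cholesterol supply genes was 1.21 to 1.40 without a replicate, 1.06 with equal peak numbers, 1.22 with reciprocal overlap and 1.95 with a peak in either library, and its ratio of shares to CpG-matched lists was 1.22. For cortex identity and zonation it was 0.675 with the stricter peaks, 0.866 with equal numbers and 0.990 with reciprocal overlap, and for medulla chromaffin genes 0.571, 0.850 and 0.972. For endothelial genes it was 0.434 to 1.01 without a replicate.

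Without a replicate the distal ratio ranged from 0.777 to 1.31 for cholesterol synthesis, 1.12 to 1.19 for cortex identity and zonation, 0.887 to 1.252 for endothelial, 0.797 to 1.51 for kidney, 0.796 to 1.44 for adipocyte and 0.801 to 0.917 for liver genes. With the stricter peaks it was 0.843 for liver, 0.414 for skeletal muscle and 0.971 for gonad genes. With equal peak numbers it was 1.01 for cortex identity and zonation, 0.996 for liver and 0.951 for skeletal muscle genes. With reciprocal overlap it was 1.08 for cortex identity and zonation, 0.767 for skeletal muscle and 0.837 for gonad genes. Within 50 kb of the gene body it was 1.07 for Schwann and neural crest, 1.02 for adipocyte, 0.661 for liver, 0.899 for gonad and 1.13 for photoreceptor genes.

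Against GC-matched windows the odds ratio was 7.0 for PHOX2 and 1.12 for GATA in distal peaks, and 1.05 for GATA in promoter peaks. With the stricter peaks it was 0.984 for NR5A in distal peaks. For the scrambled control in footprints it was 0.863 to 1.04 without a replicate. Among TSS signals of named genes, 357 values kept within the spread between the libraries and 18 moved beyond it. The values without a replicate kept within it by construction, since with 2 libraries each lies closer to the mean than the SD. The count of 357 is therefore no measure of stability. Depth per library is not given in the sources used here, so what it limits could not be computed.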

Other observations

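The tests of depth, of signal at the same sites, of the strongest distal peaks in groups of 3 and 2, of signal ratios in distal and promoter peaks apart, and of signal ratios matched on GC content were chosen after the result was seen.

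Replicate 2 held 1.90 times as many peaks as replicate 1. Depth could not be excluded: the library totals read from the signal steps stood at a ratio of 0.970 if the signal is scaled to library size, but its scaling is not given in the sources used here. Signal at the 34770 sites that overlapped 1 to 1 was a median of 2.06 times as high in replicate 2, 2.24 times at distal peaks and 1.95 times at promoter peaks, and higher enrichment and another scaling cannot be told apart. A different mix of cell types stays open too: among lists of other cell types the smallest adjusted p was 0.202, for medulla chromaffin genes, with a median ratio of 1.62 against 1.90 at random peaks, and kidney genes stood at 1.58 against 1.90. Beyond the mix of cell types, no biological explanation was tested, because there is 1 group.

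Signal ratios of replicate 2 over replicate 1 were also set against random peaks for the other lists. Of 16 lists with at least 5 peaks, 0 differed at an adjusted p below 0.05; steroidogenesis and cholesterol supply genes had the smallest unadjusted p, 0.0170, with a median ratio of 1.89 against 2.19. In distal peaks alone this list stood at 1.81 against 2.31 and immediate early and cAMP response genes at 2.10 against 2.52, both with an adjusted p of 0.0312. In promoter peaks alone both lists went the other way, at 2.32 against 2.01 and 2.36 against 2.09, with adjusted p of 0.333 and 0.207. Against random peaks matched on GC content, imprinted genes stood at 2.27 against 1.84 (adjusted p of 0.0448).

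A hypothesis was that the NR5A motif is more frequent in distal peaks near steroidogenesis and cholesterol supply genes than in others; binding was not tested. The NR5A motif stood in 4 of 25 such peaks, nearest to Scarb1 (3407 bp), Fdx1 (27455 bp), Cyp11a1 (2780 bp) and Mc2r (133475 bp, inside another gene), and in 3.77% of the other distal peaks, an odds ratio of 4.86 (1.66 to 14.2). The two-sided Fisher's exact test gave p = 0.0137 and an adjusted p of 0.0548 over 4 such tests, which misses the threshold. The match near Cyp11a1, TCAAGGCCA, lay in an intron on chromosome 9 from 58009145 to 58009153.

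The other 3 motif tests decided nothing, because the peaks were few. The NR5A motif stood in 0 of 32 distal peaks near cortex identity and zonation genes, against 3.80% of others (Fisher's exact test, adjusted p = 0.845). GATA stood in 1 of 20 near medulla chromaffin genes, an odds ratio of 1.62 (0.216 to 12.1), and ETS in 0 of 19 near endothelial genes, with adjusted p at 0.845 and 1 in Fisher's exact test. The share of distal peaks with an NR5A motif was also set against peak strength, on the idea that it rises with signal. It fell instead, from 5.44% in the weakest of 5 groups of equal size to 1.81% in the strongest, a ratio of 0.333 (0.251 to 0.443). Neither the scrambled string nor control windows were counted per group, so whether the fall is particular to the NR5A motif was not tested.

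The 5 strongest distal peaks were searched for sequence found more than once in the assembly, which can gather reads from several places. The share of repeated 36-mers was 66.7% for the peak nearest to Lars2, 57.1% for Igf2bp3 and 66.7% for Il31ra, and a median of 57.1% over all 5. These 3 shares rest on 6, 7 and 6 36-mers. Sequences of the assembly outside the chromosomes were searched as well, so a second copy need not be a separate place. Shared sequence may still raise the signal of those 3 peaks, whose lowest share was 57.1%. For the peaks nearest to Cox14 and Ubqln1 the share was 0%, which argues against exact copies of the 36-mers searched. Near-identical copies were not searched for, and what made these 2 peaks strong stays open. No biological explanation was tested.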
